A study of Mus musculus with 12 samples.

How the data were processed

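Total RNA of R1 mouse ESCs was labelled with biotin and hybridised to Affymetrix mouse gene arrays, 1 array per sample and 12 in all. The samples fell into 5 groups: ESC scrambled (2 arrays), ESC KD1 (2), ESC KD2 (2), retinoic acid scrambled (2) and retinoic acid KD1 (4). The treatment protocol speaks of knockdown and control clones, and the source names of infected cells. KD2 after retinoic acid was not analysed here. The groups follow the sample titles, and replicates are named by the number in the title.

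The deposited values are log2 probe set summaries, and the submitters' processing notes name RMA as the tool. The version and settings of RMA, the background correction and the annotation are not given in the sources used here. The array medians ran from 4.73 to 5.09, so the arrays do not share 1 distribution, and no further scaling was applied in the main analysis. The table held 35556 probe sets. Of these 23410 were listed in the platform's gene table, 21789 of them with 1 gene symbol and 1621 with several, and 12146 were not listed. Entrez identifiers matched the reference gene table for 21698 probe sets, and 0 symbols changed. Probe sets with 1 symbol gave 19938 genes. For the 999 genes with several probe sets the one with the highest mean log2 value over all arrays was used. A gene was tested when it lay above percentile 40 of the named genes on at least 2 arrays, which left 12988 genes. Chromosomes were taken from the reference gene table, and no coordinates were used.

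The comparisons, gene lists, thresholds and rule for named genes were fixed before the data were examined. A group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 7 residual degrees of freedom and a prior of 4.58. There were 8 contrasts: the mean of both lines, KD1 and KD2 each against scrambled in ESCs, KD2 against KD1, differentiation in scrambled and in KD1 cells, KD1 against scrambled after retinoic acid, and the interaction. Called genes had a Benjamini-Hochberg adjusted p under 0.05 within a contrast, two-sided. Fitting all groups together pools the spread, since each group has 2 to 4 arrays.

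The 20 hand-written gene lists cover pluripotency, primed epiblast, extraembryonic endoderm, trophectoderm, mesoderm and primitive streak, neural, Hox, retinoic acid response, germline, imprinted, polycomb, BAF complex, p53 target, cell cycle, glycolysis and hypoxia, cholesterol synthesis, amino acid stress, interferon response, feeder and fibroblast, and 2-cell-like genes. A list needed 5 tested members. The 2-cell-like list had 1 and was not tested. The other 19 were tested with limma camera (preset correlation 0.01, two-sided), adjusted over lists within a contrast, and again with an estimated correlation and with fry.

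Smarcd1 is named in every comparison. Other named genes are the 10 largest increases and 10 largest decreases past the threshold with no overlap between the arrays of the groups compared. For the interaction passing the threshold was enough. Predicted genes, small or structural RNAs and olfactory or vomeronasal receptors were left out. Of each list described, up to 4 members with the largest change past the threshold are named. Some genes the rule gave are not named in the text.

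Effects were also compared across genes by Pearson correlation, covariance and shared calls. For KD1 and KD2 in ESCs, which share their scrambled arrays, 100 simulated unchanged groups gave a background of noise alone. Alternatives covered the filter on dim genes, cyclic loess, median centring, an intensity trend, array weights, fits to the compared arrays alone, the handling of several probe sets, a 2-fold minimum, an adjusted p under 0.01, a replicate block, grouping by source name, subsets of the retinoic acid KD1 arrays, and leaving out each array in turn. Leaving out both KD2 arrays, or the genes of chromosomes 8, 14, X and Y, was added after seeing the data. The number of arrays limits the precision. Tested on simulated data, the ESC contrast of the mean of both lines recovered 38 of 50 genes changed by 1 log2 unit and 3 of 50 changed by 0.5, with 10 false calls among 12788 unchanged genes. For retinoic acid KD1 against scrambled it recovered 40 and 3 of 50, with 7 false calls. The simulated arrays shared the same spread for each gene, whereas array weights were 0.137 on each KD2 array and at least 1.165 on the others. The simulated false calls therefore do not describe contrasts that use the KD2 arrays. Every other contrast draws on a pooled spread that includes these arrays, so the simulation does not fully describe those either. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9.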

Results

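Gene expression was measured on 12 Affymetrix mouse gene arrays hybridised with labelled RNA from R1 embryonic stem cells (ESCs), a mouse line of male origin that grows on a layer of embryonic fibroblasts whose division has been blocked with mitomycin. The cells carried either a scrambled control or a knockdown of Smarcd1, which encodes BAF60a, a subunit of the SWI/SNF (BAF) chromatin remodelling complexes. Knockdown lines were labelled KD1 and KD2. Undifferentiated ESCs gave 2 scrambled, 2 KD1 and 2 KD2 arrays. Cells kept without leukemia inhibitory factor and with 1 µM retinoic acid, and labelled as differentiated for 4 days, gave 2 scrambled and 4 KD1 arrays. The deposited log2 values ran from 1.74 to 13.57, and the number of arrays per group limits the precision of every value. The labels call the arrays of a group biological replicates without saying how the cultures were kept apart, so the p-values measure the spread between these arrays, which may be partly technical. All scrambled arrays carry the same label, so the arrays replicate lines rather than the knockdown. Other differences between the lines cannot be told apart from an effect of Smarcd1 knockdown. Log2 changes are given as the estimate ± its SE from limma, with Benjamini-Hochberg adjusted p, over 12988 tested genes.

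The targeted gene was examined first, since it checks the labels. Smarcd1 stood at 8.67 ± 0.00 (SD, n = 2) in scrambled ESCs and at 7.77 ± 0.02 (SD, n = 2) in KD1 ESCs. Of the KD2 arrays, replicate 2 read 7.16, while the array labelled KD2 replicate 1 read 8.56, close to both scrambled arrays at 8.67 and 8.68. After retinoic acid, Smarcd1 was 8.74 ± 0.15 (SD, n = 2) in scrambled cells and 6.48 ± 0.10 (SD, n = 4) in cells labelled KD1. The change with knockdown was -2.26 ± 0.28 (SE, limma adjusted p = 0.000152) after retinoic acid, and all 4 knockdown arrays lay below both scrambled arrays. In ESCs it was -0.86 ± 0.28 (SE, limma adjusted p = 0.106) for the mean of the lines. It was -0.91 ± 0.33 (SE, limma adjusted p = 0.23) for KD1 and -0.81 ± 0.33 (SE, limma adjusted p = 0.152) for KD2, so the ESC changes did not pass the threshold. Without the array labelled KD2 replicate 1 the mean change was -1.21, with an adjusted p of 0.000197. The KD1 change of -0.91 had an adjusted p of 0.00196 without either KD2 array, 0.0316 with only the KD1 and scrambled ESC arrays and 0.00239 with array weights. KD2 replicate 2 alone gave -1.52 with an adjusted p of 0.000201, and the array labelled KD2 replicate 1 alone gave -0.11 with an adjusted p of 0.607. Without KD2 replicate 2 the mean change was -0.51, with an adjusted p of 0.00914. KD2 against KD1 gave 0.10 ± 0.33 (SE, limma adjusted p = 0.939), but -0.61 (adjusted p = 0.00997) without KD2 replicate 1 and 0.80 (adjusted p = 0.00676) without replicate 2. On differentiation Smarcd1 changed by 0.07 ± 0.33 (SE, limma adjusted p = 0.896) in scrambled cells, where it was -0.04 without retinoic acid replicate 1, -0.05 after cyclic loess and -0.09 after median centring. In KD1 cells it changed by -1.29 ± 0.28 (SE, limma adjusted p = 0.00265). The difference between these was -1.35 ± 0.43 (SE, limma adjusted p = 0.0855), with an adjusted p of 0.000358 without either KD2 array. Because the array labelled KD2 replicate 1 goes against its label, every direction given below for KD2 or for the mean of the lines rests partly on that array.

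**Figure D1:**
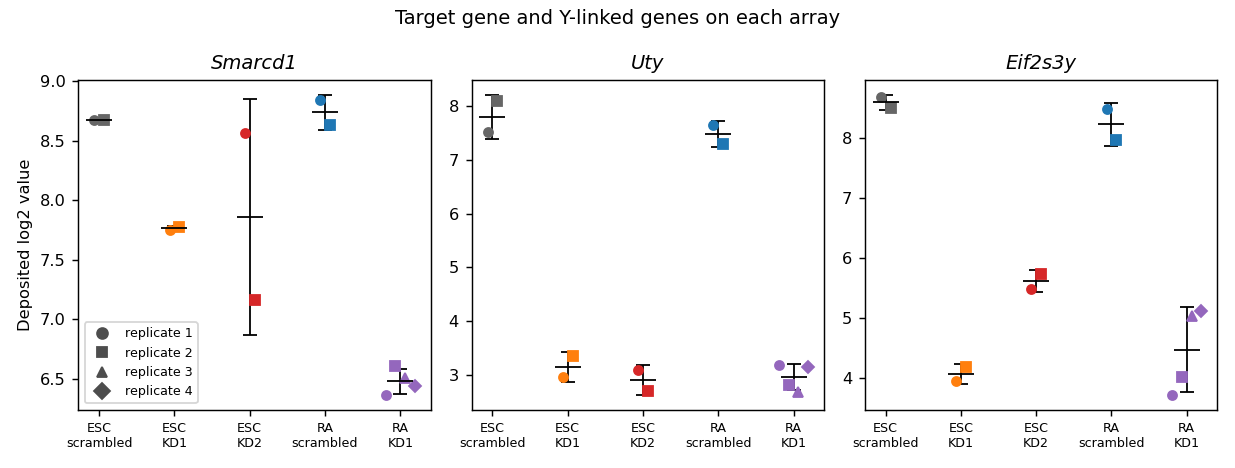
Deposited log2 value (vertical axis) of Smarcd1, Uty and Eif2s3y in the 5 groups of arrays (horizontal axis; RA, 4 days of retinoic acid); each symbol is 1 array, with the group mean and SD in black. Smarcd1 on the array labelled KD2 replicate 1 lies at 8.56, near the scrambled arrays, while the Y-linked genes Uty and Eif2s3y are low on all 8 knockdown arrays.

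The first comparison asked how the ESC transcriptome differs between the knockdown lines and scrambled cells, with both knockdown lines given equal weight. Among the increases, the noncoding RNAs Meg3 and Rian of the Dlk1-Dio3 imprinted region rose by 2.59 ± 0.17 (SE, limma adjusted p = 1.61e-05) and 2.45 ± 0.34 (SE, limma adjusted p = 0.00177). Also higher were the calcium pump Atp2a3 (2.32 ± 0.30) and Spry4, a feedback inhibitor of FGF signalling (2.22 ± 0.23). Further increases were seen for Igsf21 (2.19 ± 0.29), Mmrn2 (2.00 ± 0.26), the peptide transporter Slc15a1 (1.94 ± 0.43) and the growth factor gene Bmp4 (1.79 ± 0.29). Lower were the Y-linked genes Uty (-4.77 ± 0.22, adjusted p = 1.29e-06) and Eif2s3y (-3.77 ± 0.35) and the X-linked Usp26 (-3.14 ± 0.24). So were the lysophosphatidic acid receptor gene Lpar4 (-2.88 ± 0.22), Cyp1a1 (-2.71 ± 0.60) and the calcitonin receptor gene Calcr (-2.64 ± 0.41). Mmp25 (-2.63 ± 0.34), Cd24a (-2.63 ± 0.28) and the fatty acid transporter gene Slc27a2 (-2.54 ± 0.30) were lower as well. In all, 807 genes passed an adjusted p of 0.05, 252 higher and 555 lower.

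By gene list, 5 of the 13 tested genes of the primed epiblast list fell and 0 rose (9 fell and 1 rose adjusted over the list alone). The list had a median of -0.78 with camera adjusted p = 2.76e-05 and adjusted p = 0.471 with an estimated correlation. Without scrambled replicate 2 the median was -0.55 (adjusted p = 0.00963), and in KD1 alone -0.08 (adjusted p = 0.109, against -0.67 and 0.000374 with all arrays). Without scrambled replicate 1 it was -1.27. Lower members included Fgf5, a marker of the epiblast after implantation, at -2.88 ± 0.17 (SE, limma adjusted p = 9.53e-06), Sox4 (-1.54 ± 0.21), Sfrp2 (-1.45 ± 0.32) and Cldn6 (-1.45 ± 0.24). In the pluripotency list of 29 genes 3 rose and 1 fell (7 and 2 adjusted over the list alone). Tbx3 (1.96 ± 0.30), Klf4 (1.68 ± 0.32) and Zfp57 (1.60 ± 0.20) rose, and Dppa3 fell (-1.23 ± 0.15). For the pluripotency list the median was 0.38, with camera adjusted p = 0.00233, adjusted p = 0.471 with an estimated correlation, and adjusted p = 0.0519 with a median of 0.17 without scrambled replicate 2. Of 20 p53 target genes, 5 rose (9 rose and 1 fell adjusted over the list alone). For the p53 target list the median was 0.45, with camera adjusted p = 3.23e-06 and adjusted p = 0.179 with an estimated correlation. Changed members included Perp (1.22 ± 0.27), Zmat3 (0.93 ± 0.14), Pmaip1 (0.88 ± 0.23) and Trp53inp1 (0.56 ± 0.14). Markers of feeder cells and fibroblasts had a median of -0.57 over 28 genes (camera adjusted p = 8.54e-06, and 0.471 with an estimated correlation). In that list 3 genes were lower, and 5 adjusted over the list alone: Acta2 (-1.59 ± 0.35), Mmp2 (-1.16 ± 0.30) and Tagln (-1.06 ± 0.22) passed over all genes. The cholesterol synthesis list had a median of -0.37 (camera adjusted p = 0.00233, and 0.471 with an estimated correlation). Of its 20 genes 1, Msmo1, was past the threshold at -0.75 ± 0.20, and 0 adjusted over the list alone. The imprinted list did not pass: 2 of 26 genes rose and 3 fell (2 and 6 adjusted over the list alone), with a median of -0.23, camera adjusted p = 0.235 and adjusted p = 0.637 with an estimated correlation.

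The ESC count depended on single arrays. It was 165 without scrambled replicate 2 and 445 and 472 without KD1 replicates 1 and 2. It was 2797 and 3218 without KD2 replicates 1 and 2. With limma it was 15 when only the 6 ESC arrays were fitted, and centring each array on its median gave 325 higher and 457 lower.

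Taken line by line, KD1 ESCs had 301 genes past the threshold (118 higher, 183 lower). Beside Meg3 (3.34 ± 0.20, adjusted p = 1.15e-05) and Rian (2.73 ± 0.39), the endocytic receptor gene Cubn (2.92 ± 0.54), the proteoglycan gene Srgn (2.77 ± 0.29), the adaptor gene Dab2 (2.05 ± 0.23) and the endoderm transcription factor gene Gata6 (1.66 ± 0.27) rose. These 4 belong to the extraembryonic endoderm list, of which 6 of 25 genes rose in KD1 (10 rose and 1 fell adjusted over the list alone). For the extraembryonic endoderm list the median was 0.20, with camera adjusted p = 2.16e-07 and adjusted p = 0.256 with an estimated correlation. That median was 0.36 and 0.33 without scrambled ESC replicates 1 and 2, and 0.31 and 0.40 without KD1 replicates 1 and 2. Adgrg6 (2.20 ± 0.29) and Gprc5a (2.12 ± 0.41) were also higher. Fgf5 (-2.81 ± 0.20), Klhl4 (-2.42 ± 0.24), the zinc transporter gene Slc39a8 (-2.42 ± 0.23), St6gal2 (-2.30 ± 0.37) and the carbonic anhydrase gene Car14 (-2.29 ± 0.26) were lower. The KD1 count was 61 without scrambled ESC replicate 2, and 26 and 45 without KD1 replicates 1 and 2. It was 1057 without either KD2 array, 183 without either scrambled array of the retinoic acid groups, and 198, 197 and 181 without retinoic acid KD1 replicates 1, 2 and 4.

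The arrays labelled KD2 had 1302 genes past the threshold (374 higher, 928 lower). The 2 KD2 arrays were less alike (Pearson correlation 0.918) than either was to any scrambled or KD1 ESC array (0.923 to 0.968). The potassium channel gene Kcnma1 had the highest change at 5.27 ± 1.04 (SE, limma adjusted p = 0.00909), reading 7.37 and 9.14 on the KD2 arrays and 2.88 and 3.09 on the scrambled arrays. The hypoxia-inducible factor gene Epas1 (2.09 ± 0.18), Tgfbi (2.21 ± 0.38) and Mras (2.08 ± 0.29) were higher. The gap junction gene Gja1 (-3.10 ± 0.18), the Nodal antagonist gene Lefty1 (-3.05 ± 0.28) and Car4 (-3.02 ± 0.72) were lower. Of 20 cholesterol synthesis genes 5 fell (6 adjusted over the list alone). Members included Msmo1 (-1.17 ± 0.23), Cyp51 (-1.13 ± 0.31), Sqle (-0.95 ± 0.25) and Ebp (-0.88 ± 0.22). The list had a camera adjusted p of 0.00143 and an adjusted p of 0.465 with an estimated correlation. The rise of extraembryonic endoderm genes in KD1 was not seen in KD2. Of 25 members 0 rose and 3 fell, with a median of -0.08 and camera adjusted p = 0.362. The mean of that list was 5.959 and 5.717 on the KD2 arrays, against 6.125 and 6.05 on the scrambled arrays. The KD2 calls drew their error from the whole set of arrays. With only the 2 KD2 and 2 scrambled arrays, limma called 0 genes, with 1288 at an unadjusted p under 0.05. With array weights it called 6. The count was 4463 and 3961 without KD2 replicates 1 and 2 and 333 without scrambled replicate 2. The calls split into 498 higher and 740 lower after cyclic loess and 532 higher and 668 lower after median centring.

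Across genes, which are not independent replicates, the KD1 and KD2 changes in ESCs had a Pearson correlation of 0.671. Unchanged groups simulated 100 times against the same scrambled arrays gave a mean correlation of 0.502 with a highest value of 0.526. The covariance was 0.128 against a simulated mean of 0.0301, a difference of 0.0983. The lines shared 79 genes called higher and 155 called lower, where independent lists would share 3.4 and 13.1. The simulation gave a mean of 0.05 shared calls in all, a low value fixed by its design, since no simulated gene was changed. Its arrays also shared the same spread for each gene, whereas array weights were 0.137 on each KD2 array. The simulated correlation and shared calls are therefore not a full background for these lines. With a separate scrambled array for each line, averaged over both ways, the correlation with KD1 was 0.513 for the array labelled KD2 replicate 1 and 0.296 for KD2 replicate 2. With shared scrambled arrays it was 0.429 without the array labelled KD2 replicate 1 and 0.678 without KD2 replicate 2. The simulation with a single KD2 array gave a mean of 0.411 and a highest value of 0.44, and the value without replicate 1 lay within that range. This cannot decide whether KD2 replicate 2 shares changes with KD1, since the simulated groups carried only noise and no changes of their own. The 0.296 for KD2 replicate 2 with separate scrambled arrays does not rest on a shared array. Both scrambled arrays carry the same label, however. Any difference of the scrambled cells from both lines, such as the chromosome 8 shift given below, can therefore add to it.

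The lines were also compared directly, to ask whether they differ. Extraembryonic endoderm genes were lower in KD2 than in KD1: 7 of the 25 list genes fell and 0 rose (14 fell adjusted over the list alone). For the extraembryonic endoderm list the median was -0.69, with camera adjusted p = 6.27e-09 and adjusted p = 0.313 with an estimated correlation. The leading members were Srgn (-3.42 ± 0.29, adjusted p = 0.000775), Cubn (-3.01 ± 0.54), Dab2 (-2.58 ± 0.23) and the endocytic receptor gene Lrp2 (-2.44 ± 0.44). Lower in KD2 were also Fmr1nb (-2.98 ± 0.59), Usp26 (-2.22 ± 0.28) and the amino acid transporter gene Slc43a1 (-1.98 ± 0.33). The same held for Pnma5 (-1.90 ± 0.28), the Notch ligand gene Dll1 (-1.71 ± 0.33) and Slc27a2 (-1.71 ± 0.35). Kcnma1 (5.37 ± 1.04), Myof (2.00 ± 0.18), Nynrin (1.40 ± 0.27), Usp46 (1.31 ± 0.31), Mcf2 (1.30 ± 0.28) and Rnf17 (1.29 ± 0.30) were higher in KD2. So were the histone genes H2bc18 (1.56 ± 0.15), H2bc3 (1.39 ± 0.17), H2bc14 (1.29 ± 0.20) and H4c6 (1.26 ± 0.16), which have near-identical copies that the probes may not tell apart. Of the 351 genes past the threshold 66 were higher and 285 lower in KD2, against 51 and 115 after cyclic loess and 48 and 126 after median centring. With only the 4 arrays compared limma called 0 genes (782 at an unadjusted p under 0.05). With array weights it also called 0 (458 at an unadjusted p under 0.05). The count was 19 and 4 without KD1 replicates 1 and 2, and 4550 and 2093 without KD2 replicates 1 and 2. It was 205 without either retinoic acid scrambled array, and 196, 201, 192 and 190 without retinoic acid KD1 replicates 1, 2, 3 and 4.

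Differentiation of the scrambled cells gives the background against which the knockdown is read. After 4 days of retinoic acid, 5079 genes passed the threshold (2914 higher, 2165 lower). Of 29 pluripotency genes 25 fell and 1 rose (26 and 1 adjusted over the list alone). For the pluripotency list the median was -3.02, with camera adjusted p = 6.62e-16 and adjusted p = 0.0538 with an estimated correlation. In front were the Nodal co-receptor gene Tdgf1 (-6.31 ± 0.64, adjusted p = 2.05e-05), Nr0b1 (-5.30 ± 0.66), Gdf3 (-4.91 ± 0.30) and Utf1 (-4.64 ± 0.31). Of 24 retinoic acid response genes 17 rose (18 adjusted over the list alone). For the retinoic acid response list the median was 3.30, with camera adjusted p = 2.03e-10 and adjusted p = 0.0538 with an estimated correlation. Members included the homeobox genes Meis1 (5.42 ± 0.18, adjusted p = 3.13e-08) and Meis2 (5.41 ± 0.21), the nuclear receptor gene Nr2f2 (5.18 ± 0.21) and the retinoic acid receptor gene Rarb (4.57 ± 0.28). Hox genes, which pattern the body axis, rose for 23 of 27 members (24 adjusted over the list alone). For the Hox list the median was 1.64, with camera adjusted p = 6.23e-12 and adjusted p = 0.0538 with an estimated correlation. Examples were Hoxa5 (5.25 ± 0.39), Hoxc5 (4.66 ± 0.28), Hoxb2 (3.48 ± 0.19) and Hoxc8 (3.10 ± 0.28). Imprinted genes went up in 16 and down in 2 of 26 cases (17 and 3 adjusted over the list alone). For the imprinted list the median was 0.96, with camera adjusted p = 8.25e-05 and adjusted p = 0.0538 with an estimated correlation. Examples were the growth regulators Dlk1 (5.44 ± 0.23), Igf2 (4.90 ± 0.26) and Plagl1 (4.84 ± 0.25). Extraembryonic endoderm genes rose for 13 of 25 members (13 adjusted over the list alone). For the extraembryonic endoderm list the median was 0.74, with camera adjusted p = 0.0017 and adjusted p = 0.405 with an estimated correlation. Members included Plat (4.08 ± 0.28), Dab2 (4.02 ± 0.23) and Gata6 (3.67 ± 0.27). Glycolysis and hypoxia genes fell for 11 and rose for 2 of 25 (11 and 2 adjusted over the list alone). For the glycolysis and hypoxia list the median was -0.46, with camera adjusted p = 0.00294 and adjusted p = 0.429 with an estimated correlation. Examples were Pfkp (-4.01 ± 0.37), Pdk1 (-2.42 ± 0.22) and the glucose transporter gene Slc2a3 (-2.29 ± 0.22). Outside these lists, the myelin gene Pmp22 rose (4.52 ± 0.35). The thyrotropin-releasing hormone gene Trh (-7.90 ± 0.30), the amino acid transporter gene Slc7a3 (-6.42 ± 0.30) and the Nodal antagonist genes Lefty2 (-6.36 ± 0.32) and Lefty1 (-6.12 ± 0.28) fell. Slc27a2 (-6.06 ± 0.35), Liph (-5.13 ± 0.29), Enpp3 (-5.07 ± 0.27) and Pla2g1b (-5.05 ± 0.46) fell too. The count was 3341 without retinoic acid scrambled replicate 2. Median centring turned the split to 2421 higher and 2749 lower, with the median change of all genes moving from 0.07 to -0.09.

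In the cells labelled KD1, differentiation changed 6596 genes (3819 higher, 2777 lower). Pluripotency genes fell for 23 and rose for 1 of 29 (23 and 1 adjusted over the list alone). For the pluripotency list the median was -3.18, with camera adjusted p = 4.11e-11 and adjusted p = 0.162 with an estimated correlation. Changed members included Tdgf1 (-7.87 ± 0.56, adjusted p = 7.34e-07), Nr0b1 (-6.68 ± 0.57), Esrrb (-5.29 ± 0.32) and Gdf3 (-5.25 ± 0.26). Extraembryonic endoderm genes rose for 20 and fell for 2 of 25 (23 and 2 adjusted over the list alone). For the extraembryonic endoderm list the median was 2.89, with camera adjusted p = 4.51e-10 and adjusted p = 0.162 with an estimated correlation. In front were Plat (5.03 ± 0.24, adjusted p = 6.73e-08), the endoderm transcription factor genes Gata4 (4.86 ± 0.17) and Sox7 (4.19 ± 0.42) and the basement membrane collagen gene Col4a2 (4.24 ± 0.15). Hox genes rose for 16 of 27 members (16 adjusted over the list alone). For the Hox list the median was 0.60, with camera adjusted p = 0.00165 and adjusted p = 0.377 with an estimated correlation. Retinoic acid response genes rose for 15 and fell for 3 of 24 (15 and 3 adjusted over the list alone). For the retinoic acid response list the median was 1.40, with camera adjusted p = 0.000917 and adjusted p = 0.227 with an estimated correlation. Examples were the retinoic acid degrading enzyme gene Cyp26a1 at 7.68 ± 0.83 and Rarb at 4.95 ± 0.24. Cyp26a1 read 8.90 and 4.39 on the scrambled ESC arrays. Cholesterol synthesis genes fell for 13 and rose for 2 of 20 (14 and 2 adjusted over the list alone). For the cholesterol synthesis list the median was -0.82, with camera adjusted p = 0.000428 and adjusted p = 0.227 with an estimated correlation. Members included Msmo1 (-2.44 ± 0.20) and Dhcr7 (-2.43 ± 0.20). The epithelial keratin genes Krt19 (5.35 ± 0.58) and Krt18 (4.82 ± 0.33), Vnn1 (4.98 ± 0.17), Tax1bp3 (4.91 ± 0.30), Gpx3 (4.55 ± 0.26) and Chst15 (4.54 ± 0.27) also rose. Trh (-7.90 ± 0.26), Slc7a3 (-6.39 ± 0.26), the water channel gene Aqp3 (-5.11 ± 0.37) and Jam2 (-5.09 ± 0.38) fell, as did the zinc finger genes Zfp640 (-5.66 ± 0.44) and Zfp980 (-5.03 ± 0.38), members of a family with many similar copies. Median centring gave 2863 higher and 4213 lower calls, with the median change of all genes moving from 0.06 to -0.17. Across genes the scrambled and KD1 differentiation changes, which share no arrays, had a Pearson correlation of 0.784. In both, 2259 genes were called higher and 1635 lower, where independent lists would share 856.8 and 462.9.

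The next comparison asked how retinoic acid treated cells labelled KD1 differ from scrambled ones, and here the extraembryonic endoderm genes stood out. With a single label on each side, differences between lines cannot be separated from Smarcd1 knockdown. Y-linked and chromosome 8 genes differed too, as given below. Of 25 members 21 rose and 0 fell (21 rose adjusted over the list alone). The list had a median of 2.43, a camera adjusted p of 1.1e-18 and an adjusted p of 0.049 with an estimated correlation. The transcription factor genes Sox7 (4.35 ± 0.42, adjusted p = 2.2e-05) and Gata4 (4.33 ± 0.17, adjusted p = 4.92e-08), the laminin gene Lama1 (4.16 ± 0.27) and Srgn (4.34 ± 0.25) led the list. Other large increases were those of Epas1 (4.55 ± 0.15, adjusted p = 3.28e-08), the co-receptor gene Klb (4.24 ± 0.20), Pga5 (4.11 ± 0.37) and Glipr1 (4.08 ± 0.18). The receptor tyrosine kinase gene Kit (4.02 ± 0.36) and the activin antagonist gene Fst (4.00 ± 0.23) rose as well. Hox genes were lower in the knockdown: 20 of 27 fell and 2 rose (22 and 2 adjusted over the list alone). For the Hox list the median was -1.04, with camera adjusted p = 1.62e-10 and adjusted p = 0.0726 with an estimated correlation. Members included Hoxc5 (-2.98 ± 0.25, adjusted p = 6.65e-06), Hoxc4 (-2.11 ± 0.44), Hoxb5 (-1.97 ± 0.19) and Hoxc8 (-1.94 ± 0.24). Retinoic acid response genes fell for 13 and rose for 0 of 24 (14 fell adjusted over the list alone). For the retinoic acid response list the median was -0.59, with camera adjusted p = 1.43e-07 and adjusted p = 0.0726 with an estimated correlation. Changed members included the retinoic acid synthesis gene Aldh1a2 (-3.88 ± 0.24, adjusted p = 9.12e-07), Nr2f1 (-3.14 ± 0.15), Crabp1 (-2.90 ± 0.30) and Nr2f2 (-2.10 ± 0.18). Neural genes fell for 11 of 21 (11 adjusted over the list alone). For the neural list the median was -0.57, with camera adjusted p = 1.46e-05 and adjusted p = 0.142 with an estimated correlation. Examples were Sox11 (-2.70 ± 0.24), Pax6 (-2.44 ± 0.28), Zic1 (-1.66 ± 0.17) and Ncam1 (-1.42 ± 0.23).

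**Figure D2:**
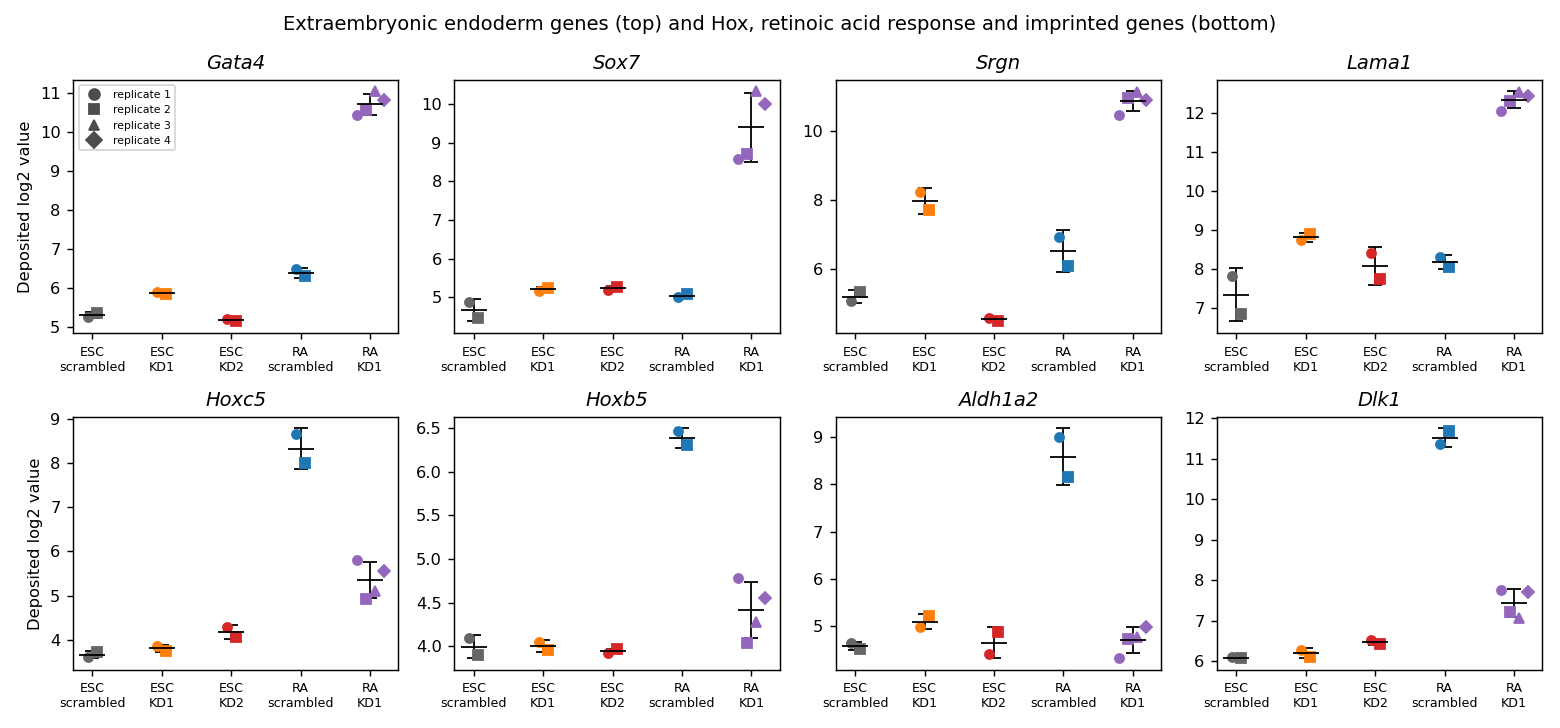
Deposited log2 values (vertical axes) of 8 genes in the 5 groups of arrays (horizontal axes; RA, 4 days of retinoic acid); each symbol is 1 array, with the group mean and SD in black. Gata4, Sox7, Srgn and Lama1 are higher on all 4 retinoic acid arrays labelled KD1 than on both scrambled ones, and Hoxc5, Hoxb5, Aldh1a2 and Dlk1 are lower.

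Among imprinted genes 12 fell and 3 rose of 26 (12 and 3 adjusted over the list alone). Dlk1 (-4.09 ± 0.20, adjusted p = 2.19e-07), Plagl1 (-3.08 ± 0.22) and Nnat (-2.59 ± 0.29) fell, while Meg3 rose (2.85 ± 0.17, adjusted p = 6.5e-07). For the imprinted list the median was -0.70, with camera adjusted p = 0.000213 and adjusted p = 0.0726 with an estimated correlation. Glycolysis and hypoxia genes rose for 15 and fell for 1 of 25 (16 and 1 adjusted over the list alone). For the glycolysis and hypoxia list the median was 0.86, with camera adjusted p = 1.14e-07 and adjusted p = 0.161 with an estimated correlation. Examples were the collagen prolyl hydroxylase genes P4ha2 (3.55 ± 0.29) and P4ha1 (2.21 ± 0.22), Bnip3 (2.77 ± 0.41) and Pfkl (2.00 ± 0.33). Cholesterol synthesis genes fell for 14 and rose for 2 of 20 (14 and 2 adjusted over the list alone). Idi1 (-2.17 ± 0.25), Msmo1 (-2.16 ± 0.20) and Tm7sf2 (-1.79 ± 0.28) fell, and Insig1, which restrains the pathway, rose (1.97 ± 0.23). For the cholesterol synthesis list the median was -1.01, with camera adjusted p = 2.14e-05 and adjusted p = 0.137 with an estimated correlation. Feeder and fibroblast genes fell for 8 and rose for 1 of 28 (10 and 1 adjusted over the list alone). For the feeder and fibroblast list the median was -0.47, with camera adjusted p = 0.00312 and adjusted p = 0.522 with an estimated correlation. Members included Mmp2 (-3.15 ± 0.30) and the collagen genes Col1a2 (-1.80 ± 0.32) and Col3a1 (-1.71 ± 0.33). Without scrambled replicate 2 the feeder list had adjusted p = 0.0733. Of 26 BAF complex genes 7 fell and 1 rose (7 and 1 adjusted over the list alone). Beside Smarcd1, Bcl7a (-1.26 ± 0.14) and Brd7 (-1.25 ± 0.22) fell, and the ATPase gene Smarca2 rose (1.94 ± 0.19). For the BAF complex list the median was -0.24, with camera adjusted p = 0.018 and adjusted p = 0.443 with an estimated correlation. That list includes the targeted gene Smarcd1 and was not tested without it. Uty (-4.51 ± 0.22), Eif2s3y (-3.77 ± 0.35), the Wnt modulator gene Sfrp1 (-4.02 ± 0.20), Crispld2 (-3.62 ± 0.25) and Lrrn1 (-3.53 ± 0.41) were lower. Lrrn4 (-3.44 ± 0.28), the transcription factor gene Foxc2 (-3.37 ± 0.12) and Upk3b (-3.35 ± 0.13) completed the largest decreases. Of the primed epiblast list 6 genes fell and 2 rose (7 and 2 adjusted over the list alone), with camera adjusted p = 0.0105 and adjusted p = 0.443 with an estimated correlation. Among p53 targets 5 rose and 1 fell (6 and 1 adjusted over the list alone), with camera adjusted p = 0.0117 and adjusted p = 0.251 with an estimated correlation. Without scrambled replicate 1 the p53 target list had adjusted p = 0.0885. The pluripotency list had 9 higher and 2 lower genes (9 and 3 adjusted over the list alone) and a median of 0.02, with camera adjusted p = 0.038, adjusted p = 0.522 with an estimated correlation, and adjusted p = 0.583 with only KD1 replicates 1 and 2. Its adjusted p was 0.0579 without scrambled replicate 1, 0.117 and 0.0836 without KD1 replicates 3 and 4, and 0.0558 without either ESC KD2 array. Cell cycle genes fell for 5 of 33 (5 adjusted over the list alone), with camera adjusted p = 0.018 and adjusted p = 0.639 with an estimated correlation. The cell cycle list had adjusted p = 0.119 without scrambled replicate 1 and 0.0702 with only KD1 replicates 3 and 4. The trophectoderm, primitive streak and mesoderm, germline, interferon response, polycomb and amino acid stress lists did not pass here, with camera adjusted p from 0.134 to 0.857. In total 2942 genes passed the threshold, 1453 higher and 1489 lower. The count was 1778 with only KD1 replicates 1 and 2 and 2112 with only replicates 3 and 4. It was 1526 and 1586 without scrambled replicates 1 and 2, and 4821 without either ESC KD2 array. Kcnma1 read 3.05 and 2.84 on KD1 replicates 1 and 2 but 6.46 and 5.95 on replicates 3 and 4, so these arrays were not alike in every gene.

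**Figure D3:**
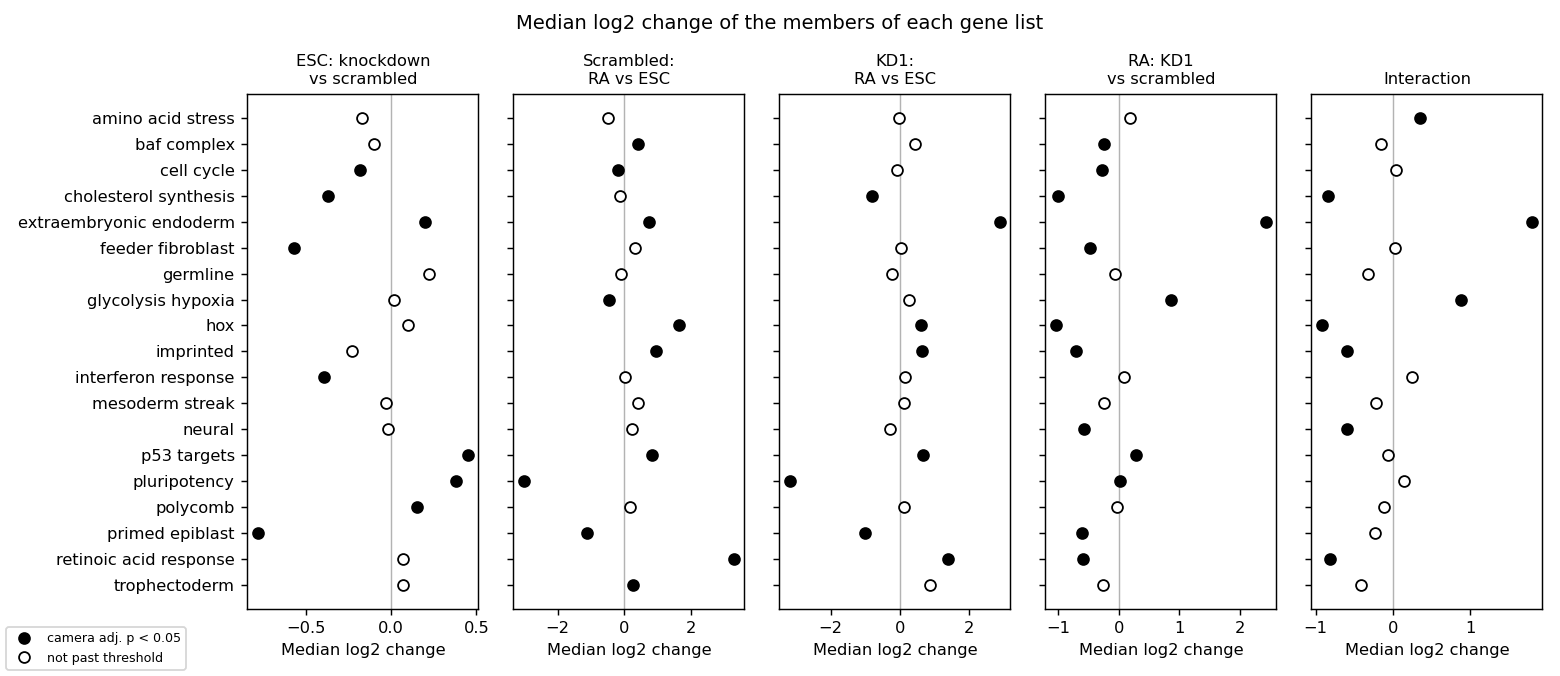
Median log2 change (horizontal axes) of the tested members of each of 19 gene lists (vertical axis) in 5 comparisons; filled symbols passed a camera adjusted p of 0.05 with the preset correlation, open symbols did not. The extraembryonic endoderm list reaches 2.43 in retinoic acid treated KD1 against scrambled cells, where the Hox list lies at -1.04.

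The interaction tested whether the change on differentiation differed between cells labelled KD1 and scrambled cells. Whether retinoic acid KD1 replicates 3 and 4 come from the KD1 line is open, as set out below. Every contrast that uses these arrays rests partly on their label. With only replicates 1 and 2, 108 of 108 named gene values in those contrasts kept their direction and side of the threshold. Most of these genes were picked for large changes on these same arrays, so this was likely beforehand. It does not settle the label of replicates 3 and 4. Over all genes the interaction calls fell from 1024 to 569. Extraembryonic endoderm genes rose more in KD1 for 15 of 25 members and less for 0 (17 more and 1 less adjusted over the list alone). For the extraembryonic endoderm list the median was 1.80, with camera adjusted p = 5.8e-13 and adjusted p = 0.0645 with an estimated correlation. Changed members included Fst (3.90 ± 0.35, adjusted p = 6.59e-05), Sox7 (3.82 ± 0.64), Gata4 (3.78 ± 0.26) and Sox17 (3.10 ± 0.32). The difference was negative for 12 and positive for 1 of 27 Hox genes (19 and 1 adjusted over the list alone). For the Hox list the median was -0.92, with camera adjusted p = 4.7e-12 and adjusted p = 0.07 with an estimated correlation. Examples were Hoxc5 (-3.12 ± 0.38, adjusted p = 0.000431), Hoxb5 (-1.98 ± 0.29), Hoxc8 (-1.87 ± 0.37) and Hoxd4 (-1.66 ± 0.22). It was negative for 10 of 24 retinoic acid response genes (12 negative and 1 positive adjusted over the list alone). For the retinoic acid response list the median was -0.82, with camera adjusted p = 4.28e-09 and adjusted p = 0.0645 with an estimated correlation. Members included Aldh1a2 (-4.39 ± 0.37, adjusted p = 5.24e-05), Nr2f1 (-3.05 ± 0.23), Crabp1 (-2.34 ± 0.45) and Nr2f2 (-2.11 ± 0.28). Glycolysis and hypoxia genes had 8 positive differences of 25 (12 adjusted over the list alone). Imprinted genes had 7 negative and 1 positive of 26 (8 and 2 adjusted over the list alone). Neural genes had 5 negative of 21 (7 adjusted over the list alone). Cholesterol synthesis genes had 5 negative and 1 positive of 20 (6 and 1 adjusted over the list alone). For the glycolysis and hypoxia list the median was 0.88, with camera adjusted p = 9.9e-08 and adjusted p = 0.221 with an estimated correlation. For the imprinted list the median was -0.59, with camera adjusted p = 0.000333 and adjusted p = 0.0742 with an estimated correlation. For the neural list the median was -0.60, with camera adjusted p = 0.000197 and adjusted p = 0.221 with an estimated correlation. For the cholesterol synthesis list the median was -0.84, with camera adjusted p = 0.00128 and adjusted p = 0.229 with an estimated correlation. The largest positive differences were those of Slc39a8 (5.11 ± 0.31, adjusted p = 9.31e-06), the vascular endothelial growth factor receptor gene Flt1 (4.95 ± 0.50), Chst15 (4.69 ± 0.41) and the carbonic anhydrase gene Car2 (4.28 ± 0.35). Adamts9 (3.87 ± 0.59), the Wnt antagonist gene Frzb (3.82 ± 0.36), Pga5 (3.82 ± 0.57) and Serpinb6c (3.80 ± 0.35) followed. The largest negative ones, after Aldh1a2, were Sfrp1 (-4.36 ± 0.31), Dlk1 (-4.20 ± 0.30), Crispld2 (-3.57 ± 0.38) and Tgfbi (-3.55 ± 0.50). Upk3b (-3.46 ± 0.20), Foxc2 (-3.28 ± 0.18), Plagl1 (-3.20 ± 0.34) and Aldh1a7 (-3.16 ± 0.31) were next. The test called 1024 genes, 555 positive and 469 negative. That count was 569 with only retinoic acid KD1 replicates 1 and 2, 648 and 666 without scrambled ESC replicates 1 and 2, and 484 and 500 without KD1 ESC replicates 1 and 2. It was 519 and 456 without retinoic acid scrambled replicates 1 and 2, and 2399 without either KD2 array.

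The KD1 change was also set side by side in ESCs and after retinoic acid, where it rests on separate arrays. Meg3, Rian, Srgn, Uty, Eif2s3y and Fgf5 moved the same way in both states, and 19 genes were called in opposite directions. Of these, Slc39a8 (-2.42 ± 0.23 in ESCs, 2.70 ± 0.20 after retinoic acid), Chst15 (-1.67 ± 0.31, 3.01 ± 0.27) and Car2 (-2.01 ± 0.27, 2.27 ± 0.23) are named after their values were seen. After retinoic acid Rian, named here after its values were seen, rose by 2.31 ± 0.34 and Fgf5 stood at -1.91 ± 0.17. Across genes the changes had a Pearson correlation of 0.284. Both states set the same labels against each other, so lasting differences between the lines can add to it. There were 44 genes called higher and 94 called lower in both states, where independent lists would share 13.2 and 21.

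Genes of some chromosomes shifted together on the knockdown arrays. Y-linked genes were examined on each array, where Uty read between 2.71 and 3.35 in knockdown ESCs against 7.51 and 8.08 in scrambled ESCs. The other tested Y-linked genes beside Eif2s3y are named after their values were seen. Uba1y read between 3.93 and 4.16 in knockdown ESCs against 5.88 and 5.14 in scrambled ESCs. Sry read between 5.34 and 5.77 in knockdown ESCs against 5.55 and 5.25, and after retinoic acid between 4.96 and 5.25 in KD1 against 5.45 and 5.48 in scrambled cells. The median of the 707 chromosome 8 genes, relative to all tested genes, was -0.298 in KD1 ESCs, -0.304 in KD2 ESCs and -0.292 in retinoic acid treated KD1 cells. These medians lay below each of 10000 random gene sets of that size matched on mean expression. Of the 555 genes lower in knockdown ESCs, 113 (20.4%) lay on chromosome 8, which holds 5.44% of tested genes. Of the 1489 lower after retinoic acid, 204 (13.7%) did. The median of the 453 chromosome 14 genes was 0.292 in KD2 ESCs and 0.009 in KD1 ESCs. That of the 418 X chromosome genes was -0.218 in KD2 ESCs, -0.084 in KD1 ESCs and 0.014 in retinoic acid treated KD1 cells. Leaving out the genes of chromosomes 8, 14, X and Y, an alternative chosen after seeing the data, left 568 called genes in knockdown ESCs and 2459 after retinoic acid.

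**Figure D4:**
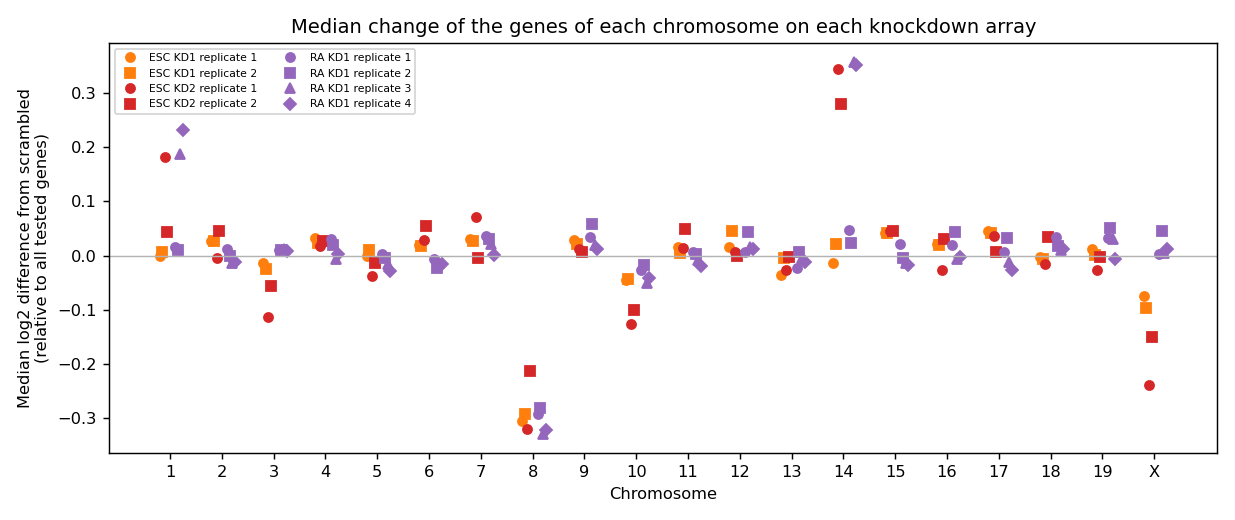
Median log2 difference from the scrambled arrays of the same state, relative to all tested genes (vertical axis), of the genes of each chromosome other than Y (horizontal axis) on each of the 8 knockdown arrays. Chromosome 8 lies between -0.329 and -0.212 on all 8 arrays, and chromosome 14 lies at 0.28 or above on both KD2 arrays and on retinoic acid KD1 replicates 3 and 4.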

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

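The tests of a compressed signal and of a gained or lost chromosome were planned before their results were seen; the tests of a scrambled array, of feeder cells, of a graded response, of a chromosome 8 dosage difference, of a KD2 origin and of array quality were chosen after the result was seen.

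Smarcd1 on the array labelled KD2 replicate 1 lay at the scrambled level. A scrambled array in its place is argued against by the Y-linked genes low on the KD1 arrays, whose median change on this array was -3.111. A signal compressed enough to hide the Smarcd1 change is argued against too. Over genes called in KD1 the slope of this array's change on the KD1 change was 0.924, against 0.791 for KD2 replicate 2. The genes were called against both scrambled arrays, which can raise both slopes. Milder compression stays open. The upper quartile of tested genes, 7.89, was the lowest of the 12 arrays, and the median of unlisted probe sets, 4.71, the highest. A culture in which the knockdown was lost or silenced, or a mixture of cells, may account for the value and was not tested.

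Genes of chromosome 8 and the Y-linked genes Uty and Eif2s3y were lower on all 8 knockdown arrays. Fewer male feeder cells cannot be told apart from other causes over the 4 tested Y-linked genes as a set. Their median change in knockdown ESCs minus that of the feeder and fibroblast list was -2.066 with a bootstrap SD of 1.334. The genes ranged from -4.77 for Uty to 0.11 for Sry. Taken alone, Uty and Eif2s3y (-3.77) fell further than that list, whose median was -0.57. A feeder loss of the size that list shows would not account for Uty and Eif2s3y, but Uba1y (-1.50) and Sry leave the set undecided. A graded response to Smarcd1 of the 3 Y-linked genes low on the KD1 arrays cannot be told apart from other causes: within state, the slope of their median change on the Smarcd1 change was -0.036 (SE 0.844) over the 8 knockdown arrays and -2.477 (SE 1.116) without the array labelled KD2 replicate 1, with few arrays that differ in Smarcd1 within a state. The chromosome 8 shift nearest to 0 on any knockdown array was -0.212. A dosage difference of that chromosome between the scrambled and knockdown cells may be present. The test of it was chosen after the result was seen and adds no support. For chromosomes other than Y, a gain or loss cannot be told apart from other causes. The smallest of the 3 chromosome 8 shifts, -0.292 with a bootstrap SD of 0.019, lay next to the bound of 0.3 set beforehand. Chromosome Y was left out of that test, and its loss was not tested. The median shift of its 4 tested genes was -3.04 in KD1 ESCs, -2.20 in KD2 ESCs and -2.14 in retinoic acid treated KD1 cells.

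Retinoic acid KD1 replicates 3 and 4 differed from replicates 1 and 2. A difference in array quality is argued against by the unlisted probe sets, whose median differed by -0.028. Over the 351 genes called between KD2 and KD1 in ESCs, the difference between these arrays had a Pearson correlation of 0.441 with the KD2 minus KD1 difference, and 212 genes had the same sign; without chromosome 14 it was 0.227 over 333 genes. The chromosome 14 shift was at least 0.28 on both KD2 arrays and replicates 3 and 4, and at most 0.047 on the KD1 ESC arrays and replicates 1 and 2, and Eif2s3y read 5.03 and 5.11 on replicates 3 and 4, 5.49 and 5.74 on the KD2 arrays, and 3.71 to 4.17 on the other arrays labelled KD1. A candidate explanation is that replicates 3 and 4 come from the KD2 line, but their chromosome 1 shift of 0.188 and 0.231 stood beside 0.181 and only 0.044 on the KD2 arrays, the KD2 shifts of chromosome 3 (-0.114 and -0.057) and X (-0.238 and -0.150) were 0.012 and 0.008, and 0.004 and 0.013, on them (the X shift of the KD1 ESC arrays, -0.074 and -0.096, was 0.003 and 0.045 on replicates 1 and 2), and a change arising within the KD1 line stays open.

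On the 4 retinoic acid KD1 arrays, 7 of 152 named genes had 1 array far from the other 3, by the ratio of its gap to the whole range: Klf4 (0.937), Liph (0.927) and Mmp25 (0.872) low on replicate 1, Meg3 high on replicate 1 (0.857), Bnip3 high on replicate 2 (0.888), and Pnma5 (0.893) and Utf1 (0.841) high on replicate 3. Chance gives about 1 in 20 groups.

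The change on differentiation differed between KD1 and scrambled cells, by the interaction test, for 1024 genes. The list medians of that difference were 1.80 for extraembryonic endoderm, 0.88 for glycolysis and hypoxia, 0.35 for amino acid stress, -0.59 for imprinted, -0.60 for neural, -0.82 for retinoic acid response, -0.84 for cholesterol synthesis and -0.92 for Hox genes. With an estimated correlation 0 of these 8 limma camera calls held, and fry gave 7 over all lists. For amino acid stress 1 of 22 genes passed, and its list call (adjusted p = 0.0274) was lost at adjusted p = 0.117 without scrambled ESC replicate 1, 0.0631 without KD1 ESC replicate 2, 0.0519 without retinoic acid scrambled replicate 1, 0.108 with a replicate block and 0.124 with only retinoic acid KD1 replicates 1 and 2. Of 152 named genes 83 passed. Positive log2 differences were those of Slc39a8 (5.11), Flt1 (4.95), Chst15 (4.69), Car2 (4.28), Fst (3.90), Adamts9 (3.87), Frzb (3.82), Sox7 (3.82), Pga5 (3.82) and Serpinb6c (3.80). Smaller ones were those of Gata4 (3.78), Epas1 (3.68), Glipr1 (3.68), Sox17 (3.10), Klb (2.95), Kit (2.87), Lama1 (2.68), Gpx3 (2.64), Tax1bp3 (2.59) and Col4a2 (2.55). Then came Klhl4 (2.49), Mmp25 (2.41), P4ha1 (2.37), Myof (2.35), P4ha2 (2.33), Bnip3 (2.31), Smarca2 (2.15), Pfkl (2.06), Insig1 (2.04) and Cldn6 (1.77). The least positive were Lpar4 (1.64), Srgn (1.57), Slc2a3 (1.52), Gja1 (1.51), Enpp3 (1.40), Lefty1 (1.32), Car14 (1.27), Dppa3 (1.08) and Vnn1 (1.06). Negative log2 differences were those of Aldh1a2 (-4.39), Sfrp1 (-4.36), Dlk1 (-4.20), Crispld2 (-3.57), Tgfbi (-3.55), Upk3b (-3.46), Foxc2 (-3.28), Plagl1 (-3.20), Aldh1a7 (-3.16), Lrrn1 (-3.12) and Hoxc5 (-3.12). Next in size were Nr2f1 (-3.05), Jam2 (-2.84), Bmp4 (-2.70), Ncam1 (-2.60), Atp2a3 (-2.39), Lrrn4 (-2.37), Crabp1 (-2.34), Aqp3 (-2.34), Mmp2 (-2.25), Spry4 (-2.18) and Igsf21 (-2.18). Below these in size came Zfp57 (-2.15), Nr2f2 (-2.11), Meis2 (-2.09), Hoxb5 (-1.98), Gprc5a (-1.96), Nnat (-1.91), Hoxc8 (-1.87), Msmo1 (-1.84), Idi1 (-1.72), Pax6 (-1.72) and Zic1 (-1.66). The smallest in size were Hoxd4 (-1.66), Sox11 (-1.63), Tm7sf2 (-1.62), Hoxb2 (-1.61), Perp (-1.59), Mmrn2 (-1.59), Igf2 (-1.26), Bcl7a (-1.23), Meis1 (-1.15), Dhcr7 (-1.10) and H4c6 (-0.75).

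KD2 and KD1 differed in ESCs for 351 genes by limma, of which 31 were among the named genes, and for 0 with only their own arrays, where 782 had an unadjusted p under 0.05. The extraembryonic endoderm list had a median difference of -0.69. Higher in KD2 were Kcnma1 (5.37), Myof (2.00), H2bc18 (1.56), Nynrin (1.40), H2bc3 (1.39), Usp46 (1.31), Mcf2 (1.30), H2bc14 (1.29), Rnf17 (1.29), H4c6 (1.26), Epas1 (1.22) and Serpinb6c (1.21). Lower in KD2 were Srgn (-3.42), Cubn (-3.01), Fmr1nb (-2.98), Dab2 (-2.58), Lrp2 (-2.44), Usp26 (-2.22), Slc43a1 (-1.98), Pnma5 (-1.90), Dll1 (-1.71) and Slc27a2 (-1.71). Smaller decreases were those of P4ha2 (-1.61), Cldn6 (-1.56), Meg3 (-1.51), Gata6 (-1.50), Lefty1 (-1.44), Gja1 (-1.17), P4ha1 (-1.08), Klb (-1.04) and Col4a2 (-0.93).

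Probe sets absent from the gene table, which the comparisons do not use, had a higher median than both scrambled arrays of their state on 6 knockdown arrays: 4.71 on the array labelled KD2 replicate 1, 4.37 and 4.55 on KD1 ESC replicates 1 and 2, against 4.34 and 4.36, and 3.96, 4.02 and 4.01 on retinoic acid KD1 replicates 1, 2 and 3, against 3.86 and 3.93. The other 2 were not above both: KD2 replicate 2 lay lower at 3.98, and retinoic acid KD1 replicate 4 between the scrambled arrays at 3.92.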

How the results depend on the processing

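Apart from leaving out both KD2 arrays or the genes of chromosomes 8, 14, X and Y, chosen after seeing the data, these alternatives were planned. Counts within 1.5 times the main value under an alternative are not listed. Counts are in the order ESC mean, KD1, KD2, KD2 against KD1, differentiation scrambled, differentiation KD1, retinoic acid, interaction where several are given. Cyclic loess gave 166 and median centring 174 genes for KD2 against KD1. Array weights gave 309, 1148, 6 and 0 for the ESC contrasts, 4988 after retinoic acid and 2548 for the interaction, with a weight of 0.137 on each KD2 array. With only the arrays compared the ESC mean gave 15, limma called 0 for KD2 (1288 at an unadjusted p under 0.05) and 0 for KD2 against KD1 (782, and 458 with array weights), and the counts were 4734 after retinoic acid and 2399 for the interaction. Testing every probe set gave 127 for KD1. A 2-fold minimum gave 337, 181, 598, 139, 2645, 3056 and 1200, with the interaction within 1.5 times. An adjusted p under 0.01 gave 281, 62, 474, 36, 3332, 1747 and 400, with differentiation in KD1 within 1.5 times. Grouping by source name gave 502 for the ESC mean. With only retinoic acid KD1 replicates 1 and 2 the counts were 1778 after retinoic acid and 569 for the interaction. Without both KD2 arrays they were 1057 for KD1, 4821 and 2399, since the spread of the KD2 pair then leaves the shared variance. Replicate numbers did not pair the samples: the deviations of replicate 1 correlated between -0.183 and 0.243 across groups, and fewer than 3 pairs exist per comparison. A replicate block gave 358, 34, 675, 29, 1619 and 447, with both differentiation counts within 1.5 times, and removes retinoic acid KD1 replicates 3 and 4, the only arrays with those numbers. Leaving out single arrays gave 165 to 3218, 26 to 1057, 333 to 4463, 4 to 4550, 3341 to 7074, 4416 to 8310, 1526 to 4821 and 456 to 2399 genes in the order above, and an array left alone in its group is assumed to vary like the others. The correlation of the KD1 and KD2 changes then ran from 0.429 to 0.756, and that of the ESC and retinoic acid changes from 0.217 to 0.302, or 0.258 without chromosomes 8, 14, X and Y. With an estimated correlation 0, 0, 0, 0, 0, 0, 1 and 0 lists passed limma camera, against 9, 10, 6, 1, 11, 8, 13 and 8 with the preset one, while fry passed 2, 2 and 3 lists in the first 3 contrasts and 13 for differentiation in KD1. Of 5370 values of named genes under the alternatives, 5030 kept their direction and side of the threshold, 321 lost and 15 gained the call, and 4 changed sign, all for Smarcd1: KD2 against KD1 was -0.61 without the array labelled KD2 replicate 1, since that array carries the scrambled level, and 0.80 without replicate 2, while its change on differentiation of scrambled cells was -0.046 after cyclic loess, -0.087 after median centring and -0.037 without retinoic acid scrambled replicate 1 (0.17 without replicate 2), and passed in none of these. The causes of the other changes were not tested, apart from those that follow from fewer genes, fewer arrays or a stricter threshold. Most named genes were picked for large changes on these arrays, so the share kept is not that of all genes. Signal over background limits the dim genes, and the filter on them left all counts within 1.5 times.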

Other observations

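These observations were chosen after the values were seen, and no test of an explanation was run on them. Dlk1 and Meg3, both of the Dlk1-Dio3 imprinted region, parted after retinoic acid. The protein-coding Dlk1 read 11.36 and 11.69 on the scrambled arrays and 7.75, 7.21, 7.08 and 7.71 on the KD1 arrays. The noncoding Meg3 read 5.68 and 6.13 on the scrambled arrays, and 8.95, 8.69, 8.71 and 8.68 on the KD1 arrays. In ESCs Dlk1 lay between 6.08 and 6.51 on all 6 arrays, while Meg3 was higher on all 4 knockdown arrays.

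The pluripotency gene Nanog differed among the retinoic acid KD1 arrays, reading 4.14 and 4.71 on replicates 1 and 2 and 7.14 and 6.94 on replicates 3 and 4, with 7.40 and 7.42 on the scrambled arrays. Pou5f1 did not part these arrays in that way, reading 6.44 and 7.28 on replicates 1 and 2 and 6.66 and 6.45 on replicates 3 and 4. The X-linked Fmr1nb read 7.99 and 7.88 on replicates 1 and 2, 6.07 and 5.91 on replicates 3 and 4, and 5.49 ± 0.15 (SD, n = 2) on the KD2 ESC arrays.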
